A study of Mus musculus with 6 samples.

How the data were processed

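The data were expression values of 6 RNA-seq libraries from adult mouse SVZ neural stem cells, 3 infected with a control adenovirus and 3 with an adenovirus carrying SETD4. Total RNA was the starting molecule, per the labels. Reads had been aligned with HISAT2 2.0.5 and the genome build was mm39, per the submitters' processing notes. The counting tool, annotation release, strand setting, library selection and read layout were not given in the sources used here. The authors deposited FPKM values, meaning reads or fragments per kilobase of gene length scaled by a library size, in a table per group with gene coordinates and gene length in bases, per the file headers. Each library had its own column, and groups and replicate numbers were taken from the sample titles.

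The values held their own depth. In each library, FPKM times gene length was a whole multiple of what 1 read was worth for 100% of values, with a tolerance of 0.05 reads, and this gave the number of reads behind each gene and the library size the authors had divided by. Recovered totals ran from 14924273 to 18078717 reads. The recovered totals over the listed genes differed from the size the authors had used by 0.634%, 2.75% and 0.639% in the controls and by -5.04%, -3.97% and -3.69% in SETD4 OE, so the authors' scaling and a scaling to equal sums are not the same. The median tested gene had 546 reads per library, and the median standard error of a log2 fold change was 0.08. Of 294 tested genes shorter than 200 bases 66 changed, and 53 of these rested on fewer than 20 reads per library.

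Since the tables hold FPKM, the test set in advance for this unit was used. Values were transformed to log2(FPKM + 1), genes with a mean of at least 1 FPKM over the 6 libraries were kept (12994 of 55802), and the groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and a two-sided test. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. No replicate block was used. Libraries of a group were first compared with each other by a chi-square test of their recovered reads, and the statistic divided by its degrees of freedom was 3.68 to 14.8 within groups and 83.0 to 109 between groups, so no pair of libraries was a repeat of the same library.

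Before the data were examined, 26 gene lists were fixed from textbook knowledge, among them markers of other cell types an SVZ culture could hold, with no gene in more than 1 list. Lists with at least 5 tested members (24) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Unless stated otherwise, the number of members called was the same when adjusted over the list alone. The named genes also followed a rule set in advance. It took Setd4, then the 6 largest rises and 6 largest falls among changed protein-coding genes with a mean of at least 5 FPKM and no overlap between the groups, leaving out predicted genes. It added up to 3 called members with the largest change from each list that passed or had at least 3 called members, and Kmt5a, Kmt5b, Kmt5c, Mki67 and Gfap whatever their test. A few genes that the rule picks are not reported here. Other members named in the text were picked after their values were seen.

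The limma step was tested on simulated reads drawn from the real means and library sizes for this comparison, with 12992 genes tested and 200 genes changed. It recovered 73 of 93 genes changed 1.5-fold (78.5%) and 95 of 97 changed 3-fold (97.9%), and called 6 unchanged genes. All simulated genes shared 1 spread between libraries (dispersion 0.00279), and far fewer genes were changed than the 7790 called in the real data. The 6 calls therefore give no error rate for the real count. The list step called the 1 list of raised genes and 0 of 100 random lists, whose genes were simulated independently, so it does not test lists of correlated genes.

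Alternatives tried were other filters on low values, a pseudocount of 0.1, the replicate number as a block, removal of mitochondrially encoded and the 10 most abundant genes, higher thresholds of change, and leaving out each library in turn. Chosen after the tables were seen were 4 other scalings (equal sums, median of ratios, upper quartile, quantile), limma-voom on the recovered reads, limma's treat and the lists described among the closing observations. Base composition for a check of GC and length bias came from mouse GENCODE transcripts of the earlier build GRCm38, matched by gene identifier and used for composition only, with a loess surface of span 0.5 and degree 2. Coordinates are those of the deposited tables. Figures were drawn with matplotlib 3.10.9.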

Results

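RNA was sequenced from primary neural stem cells of the adult mouse subventricular zone (SVZ), the region along the lateral ventricles where new neurons arise throughout life. The cells came from C57BL/6 mice and were kept in Neurobasal-type medium with the B27 supplement. They were infected for 24 h either with an adenovirus carrying SETD4 and green fluorescent protein (SETD4 OE, n = 3) or with an adenovirus carrying the fluorescent protein alone (control, n = 3). SETD4 is a SET domain protein of the lysine methyltransferase class. The study's title concerns SETD4-marked cells as a reservoir of adult stem cells, and the comparison asks how raising SETD4 alters the transcriptome of these cultures. The values were FPKM for 55802 genes, from which whole reads per gene were recovered. The control libraries held 16120766, 18078717 and 16007182 reads and the SETD4 OE libraries 14992763, 14924273 and 16045138. At least 1 FPKM was reached by 12682 ± 62.2 genes in the controls and 13207 ± 46.0 genes in SETD4 OE (mean ± SD, n = 3 each).

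Setd4 itself (ENSMUSG00000022948; mm39 chromosome 16, 93380345 to 93400951, minus strand) rose from 1.15 ± 0.329 FPKM in the controls to 325 ± 26.4 FPKM in SETD4 OE. The 3 control libraries held 82, 92 and 131 Setd4 reads, and the 3 SETD4 OE libraries held 25096, 28959 and 29822. The log2 fold change was 7.25 (SE 0.11, adjusted p = 3.283e-07, limma). Reads from the viral construct and from the endogenous gene are not separated in this value. Across the transcriptome, 7790 of 12994 tested genes changed, of which 3384 were higher and 4406 lower in SETD4 OE, and 1177 of them changed by more than 1 on the log2 scale (556 higher, 621 lower). The 3 SETD4 OE values lay outside the range of the 3 control values for 8579 tested genes, or 66.0%, where chance gives 10%. Pearson correlations of log2 values, taken across genes, were 0.985 to 0.990 within groups and 0.917 to 0.926 between them. Mitochondrially encoded genes held 3.78%, 2.45% and 2.45% of the reads in control replicates 1, 2 and 3 and 3.64 ± 0.107% in SETD4 OE; without control replicate 1, which stood apart from the other controls, 7874 genes changed, among them 7224 of the 7790.

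**Figure D1:**
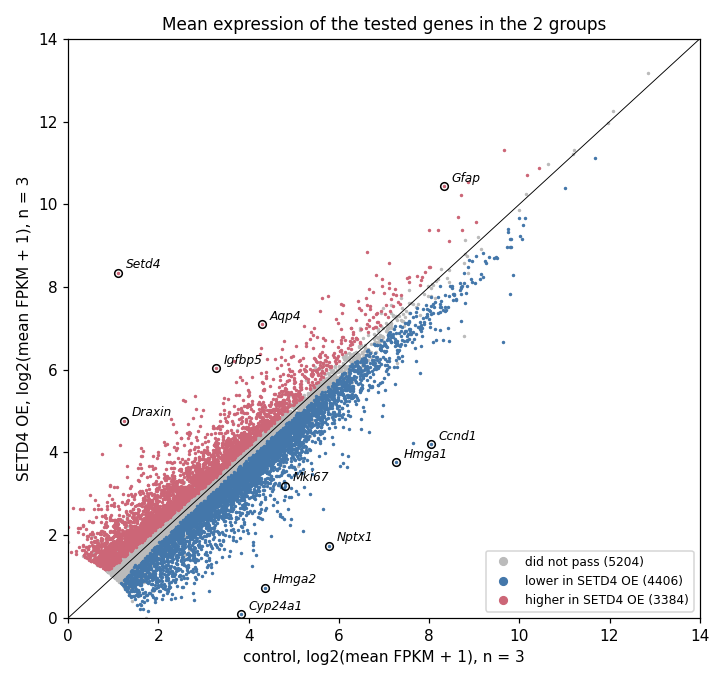
Mean FPKM of each of the 12994 tested genes in the controls (x axis) and in SETD4 OE (y axis), both as log2(mean FPKM + 1) of 3 libraries, with genes coloured by the limma test and the diagonal marking equal means. Setd4 stands far above the diagonal at 1.15 against 325 FPKM, and Ccnd1 far below it at 261 against 17.3 FPKM.

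The largest rises after Setd4 were in Draxin, a secreted axon guidance protein, Rnase1, a secreted ribonuclease, and Kcnn2, a calcium-activated potassium channel, followed by Aqp4, the water channel of astrocytes, and Igfbp5, a binding protein of insulin-like growth factors. Draxin (chromosome 4, 148182894 to 148215155) went from 1.37 ± 0.084 to 26.2 ± 0.811 FPKM, and Aqp4 (chromosome 18, 15522553 to 15544039) from 18.6 ± 3.07 to 136 ± 7.93 FPKM. Log2 fold changes were 3.52 for Draxin, 3.21 for Rnase1, 3.04 for Kcnn2, 2.82 for Aqp4 and 2.77 for Igfbp5. The largest falls were in Nptx1, a neuronal pentraxin, in Ccnd1, which encodes the G1 cyclin D1, in Cyp24a1, the vitamin D 24-hydroxylase, and in the high-mobility-group genes Hmga2, Hmga1 and Hmga1b. Ccnd1 (chromosome 7, 144483668 to 144493662) fell from 261 ± 12.3 to 17.3 ± 0.940 FPKM (log2 fold change -3.84, SE 0.06). Nptx1 fell from 54.1 ± 1.89 to 2.35 ± 0.364 FPKM, Hmga2 from 19.5 ± 0.840 to 0.662 ± 0.132 FPKM, and Cyp24a1 from 13.2 ± 0.573 to 0.0641 ± 0.0403 FPKM. The order of the falls depends on the treatment of low values. Cyp24a1 had a log2 fold change of -3.74 but reached -7.72 among the alternatives, where Nptx1 went no lower than -4.53. The values of Hmga1 and Hmga1b, with log2 fold changes of -3.48 and -3.43, are uncertain because they are near-identical copies. Several named genes also overlap another expressed gene with no strand setting given, so their values may hold reads of the neighbour: Draxin (Mad2l2), Aqp4 (Gm50048), Ccnd1 (LTO1), Cyp24a1 (Pfdn4), Hmga1 (AI413582), Mbp (Rpl21-ps8), Rrp9 (Parp3), Bmp6 (Txndc5), Map1lc3b (Zcchc14), Ctsb (Fdft1), Trim28 (Zbtb45) and Top2a (a gene without a symbol).

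Cell cycle genes were lower throughout. All 27 tested genes of DNA replication and G1/S fell, with a median log2 fold change of -1.55, and all 28 tested genes of mitosis and G2/M fell, also with a median of -1.55. Uhrf1, which couples DNA methylation to replication, fell from 26.5 ± 2.19 to 4.25 ± 0.247 FPKM. Rrm2, the small subunit of ribonucleotide reductase, fell from 67.5 ± 2.74 to 12.5 ± 0.683 FPKM, and the replicative helicase subunit Mcm5 from 25.6 ± 2.38 to 4.43 ± 0.237 FPKM. Among the mitotic genes, Aurkb had a log2 fold change of -2.27, Ube2c of -2.10 and Top2a of -2.06. The proliferation marker Mki67 fell from 26.8 ± 2.24 to 8.18 ± 0.620 FPKM (log2 fold change -1.60, SE 0.08, adjusted p = 7.872e-06, limma). The adjusted p of the list test (limma camera) was 2.27e-13 for DNA replication and 5.821e-14 for mitosis. With an estimated correlation between genes in place of the preset value, the adjusted p was 0.0509 for DNA replication, which no longer passed, and 0.0468 for mitosis.

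Most genes of the quiescent neural stem cell list moved the opposite way. Of 20 tested members, 19 rose and 1 fell, with a median log2 fold change of 1.10 (adjusted p = 2.399e-09; adjusted p = 0.0468 with an estimated correlation). Ntsr2, a neurotensin receptor of astrocytes and stem cells, rose from 4.79 ± 1.43 to 37.4 ± 0.655 FPKM. The gap junction gene Gja1 rose from 18.2 ± 1.66 to 90.5 ± 2.42 FPKM, and Id4, a helix-loop-helix inhibitor, from 6.16 ± 0.252 to 32.2 ± 1.68 FPKM. The single tested member that fell was Hes1 (log2 fold change -1.17), while its relative and fellow Notch effector Hes5 rose (2.03). Both were picked after their values were seen, as was Thbs4, below the expression threshold at 0.211 and 0.179 FPKM in control and SETD4 OE. Some members, such as Ntsr2, are shared with astrocytes, and each gene was placed in 1 list only. The list therefore does not tell quiescent stem cells from astrocytes. Most members of 3 other marker lists rose too, with medians of 1.09 for oligodendrocyte precursors, 0.77 for oligodendrocytes and 0.92 for ependymal cells, but none of the 3 lists passed with an estimated correlation (adjusted p = 0.0647, 0.123 and 0.123). A mean of at least 5 FPKM was reached by 7, 3 and 2 of their members. Low genes rose more often in the data as a whole. Of changed genes, 35.8% were higher with that filter, 43.4% in the main test and 49.5% without a filter. Genes of activated stem cells and transit-amplifying progenitors split, with 9 of 15 higher and 5 lower. Ccnd1 and Ccnd2 (124 ± 4.02 to 28.6 ± 0.950 FPKM) fell, and the Notch ligand Dll1 rose from 6.54 ± 0.153 to 23.9 ± 0.444 FPKM. The median of this list was 0.62 but turned to -0.34 over the 11 members with a mean of at least 5 FPKM (5 higher, 5 lower), its mean was -0.08, its summed level went from 2311 to 1479 FPKM, and it did not pass (adjusted p = 0.329). For the neuroblast list, 7 of 15 tested members rose and 4 fell (adjusted p = 0.357), with Sox4 at 1.30, Igfbpl1 at 0.84 and Gad2 at -0.93 on the log2 scale. Of 6 tested genes of mature neurons none rose (3 with upper-quartile scaling) and 2 fell, the neurofilaments Nefl (-2.46) and Nefm (-1.43), both picked after their values were seen; the list's median was 0.09, its mean -0.57, and it did not pass (adjusted p = 0.645).

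Among glial genes, Gfap, the intermediate filament of astrocytes and SVZ stem cells, rose from 321 ± 14.6 to 1388 ± 42.8 FPKM (log2 fold change 2.11, SE 0.07). Agt, which encodes angiotensinogen, rose from 9.89 ± 0.509 to 39.0 ± 3.62 FPKM. The astrocyte list as a whole was divided, with 6 of 13 members higher and 4 lower (9 and 2 with quantile normalization), and did not pass (adjusted p = 0.0987). Of 11 tested genes of oligodendrocyte precursors 10 rose and 1 fell, with a median of 1.09 (adjusted p = 6.008e-05; adjusted p = 0.0647 with an estimated correlation). Gpr17 rose from 2.96 ± 0.0797 to 14.3 ± 0.176 FPKM, Tnr from 2.48 ± 0.213 to 11.6 ± 0.761 FPKM, and Sox10 from 2.47 ± 0.262 to 7.73 ± 0.852 FPKM. The member that fell was Olig1, the most abundant (888 to 570 FPKM), so that the list's summed level went down from 1028 ± 30.9 to 786 ± 20.2 FPKM. Of 9 tested genes of mature oligodendrocytes 8 rose and 1, Trf, fell (log2 fold change -0.35), with a median of 0.77 (1.27 with limma-voom; adjusted p = 8.189e-04; adjusted p = 0.123 with an estimated correlation). These included the myelin genes Mbp, at 2.40 ± 0.102 and 5.84 ± 0.732 FPKM, and Cldn11, at 2.34 ± 0.344 and 5.34 ± 0.215 FPKM. All 7 tested ependymal genes rose, with a median of 0.92 (1.41 with limma-voom; adjusted p = 9.559e-04; adjusted p = 0.123 with an estimated correlation), among them Foxj1, the master regulator of motile cilia (15.8 ± 2.10 to 35.0 ± 5.11 FPKM), Tppp3 and Dynlrb2.

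Of 18 genes of microglia and macrophages 1 reached the expression threshold, and the list summed to 9.13 ± 1.58 FPKM in the controls and 8.25 ± 0.701 FPKM in SETD4 OE. That sum rests on Cd68, the 1 member above the threshold, and the other 17 summed to 2.19 ± 0.399 and 4.50 ± 0.272 FPKM. Of 14 endothelial genes 1 reached it, and the list summed to 4.88 ± 0.127 and 2.66 ± 0.171 FPKM, or without that member, Flt1, to 1.44 ± 0.0969 and 2.04 ± 0.126 FPKM. Genes of pericytes, smooth muscle and fibroblasts summed to 79.65 ± 1.32 and 64.2 ± 4.46 FPKM and went both ways, 4 of 7 higher (5 when adjusted over the list alone) and 2 lower, with the collagens Col1a1 (0.752 to 3.80 FPKM) and Col3a1 (1.13 to 3.96 FPKM) up and smooth muscle actin Acta2 (30.9 to 11.6 FPKM) down.

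**Figure D2:**
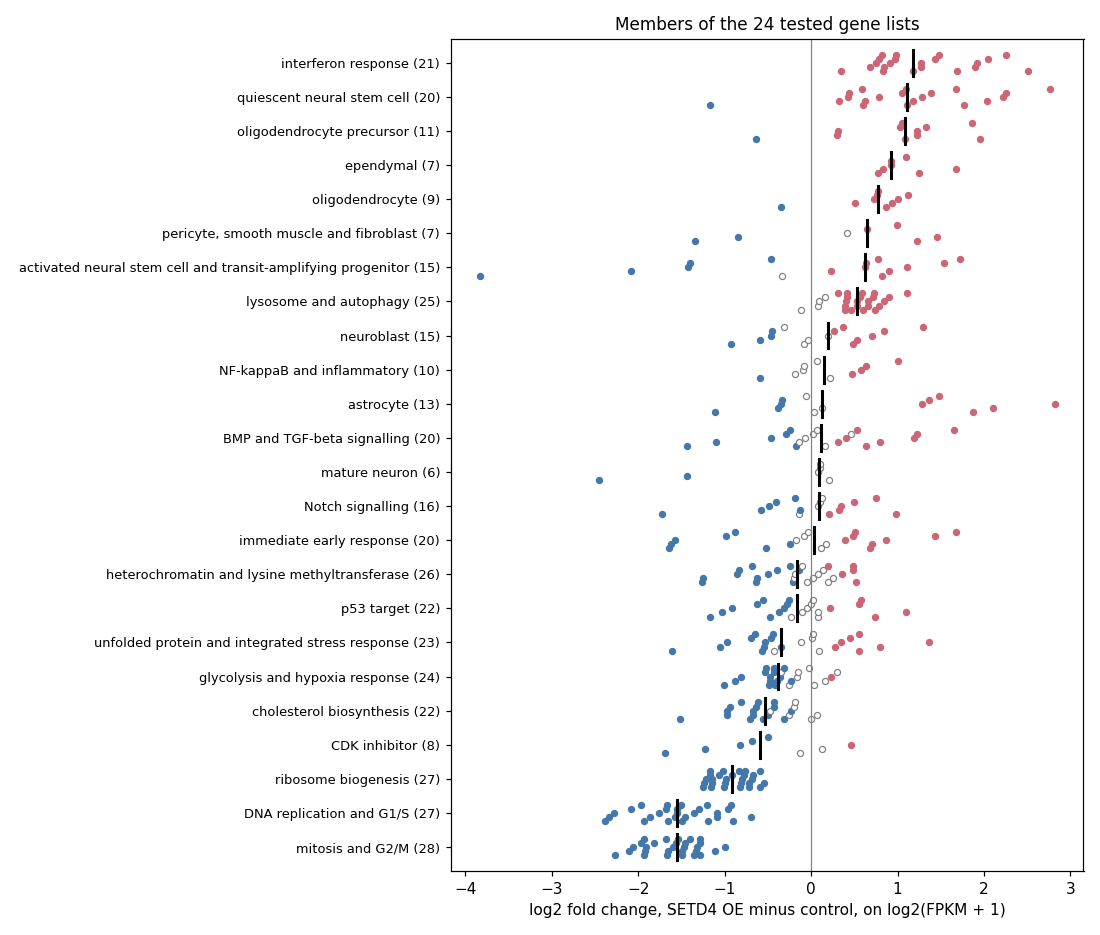
Log2 fold change (SETD4 OE minus control, on log2(FPKM + 1), x axis) of every tested member of the 24 tested gene lists (y axis, number of members in brackets), where filled points passed the limma test, open points did not, and black bars are list medians. The 28 mitosis genes all lie to the left with a median of -1.55, and the 21 interferon response genes all lie to the right with a median of 1.18.

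Interferon response genes rose as a group. All 21 tested members were higher in SETD4 OE, with a median log2 fold change of 1.18 (2.01 with limma-voom, 1.85 with a pseudocount of 0.1, 0.79 over the 5 members with a mean of at least 5 FPKM; adjusted p = 1.252e-10; adjusted p = 0.145 with an estimated correlation). The chemokine gene Cxcl10 rose from 2.04 ± 0.488 to 16.1 ± 0.616 FPKM, Isg15, a ubiquitin-like modifier, from 0.515 ± 0.0613 to 6.26 ± 1.13 FPKM, and Ifit3 from 0.497 ± 0.0266 to 5.19 ± 0.458 FPKM. Both groups had received adenovirus, and the microglia and macrophage list was at 9.13 and 8.25 FPKM in control and SETD4 OE, or at 2.19 and 4.50 FPKM without Cd68. In the NF-kappaB and inflammatory list, 4 of 10 rose and 1 fell (adjusted p = 0.273). Ccl2 was at 1.02 ± 0.550 and 2.97 ± 0.277 FPKM, Nfkbia, the inhibitor of NF-kappaB, at 21.3 ± 0.710 and 33.7 ± 0.915 FPKM, and Lif at 1.75 ± 0.334 and 0.820 ± 0.211 FPKM. Lysosome and autophagy genes were higher in 21 of 25 cases and lower in none, with a median of 0.53 (adjusted p = 4.573e-08; adjusted p = 0.0885 with an estimated correlation). Wipi1, which acts in autophagosome formation, rose from 8.52 ± 0.626 to 19.5 ± 1.08 FPKM. Map1lc3b, which encodes an LC3 protein of the autophagosome membrane, and the lysosomal protease gene Ctsb had log2 fold changes of 0.90 and 0.84.

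All 27 tested genes of ribosome biogenesis fell, with a median of -0.92 (adjusted p = 2.367e-10; adjusted p = 0.102 with an estimated correlation). The nucleolar chaperone gene Npm1 fell from 226 ± 7.95 to 94.5 ± 1.35 FPKM, Nop2 from 37.8 ± 2.60 to 15.7 ± 0.882 FPKM and Rrp9 from 19.2 ± 3.32 to 7.49 ± 0.927 FPKM. In cholesterol biosynthesis 16 of 22 genes fell (17 when adjusted over the list alone) and none rose (1 with upper-quartile scaling or quantile normalization), with a median of -0.53 (adjusted p = 6.433e-05; adjusted p = 0.420 with an estimated correlation). Hsd17b7, which acts in the later steps of the pathway, fell from 9.73 ± 0.251 to 4.48 ± 0.260 FPKM (log2 fold change -0.97). In the glycolysis and hypoxia list 15 of 24 fell and 1 rose (11 and 4 with quantile normalization). The median was -0.38, and -0.18 with quantile normalization. The adjusted p of the list (limma camera) was 8.919e-03, and 0.446 with an estimated correlation. Genes that fell included Ldha (228 ± 23.4 to 112 ± 6.15 FPKM), Eno1 (386 ± 12.2 to 209 ± 10.8 FPKM) and the hexokinase gene Hk2 (4.83 ± 0.766 to 2.30 ± 0.111 FPKM). The unfolded protein and integrated stress response list was mixed, with 7 of 23 higher and 11 lower (12 when adjusted over the list alone; adjusted p of the list 0.377). Its largest changes were the mitochondrial folate enzyme gene Mthfd2 (-1.61), the cystine transporter gene Slc7a11 (1.37) and the asparagine synthetase gene Asns (-1.06).

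**Figure D3:**
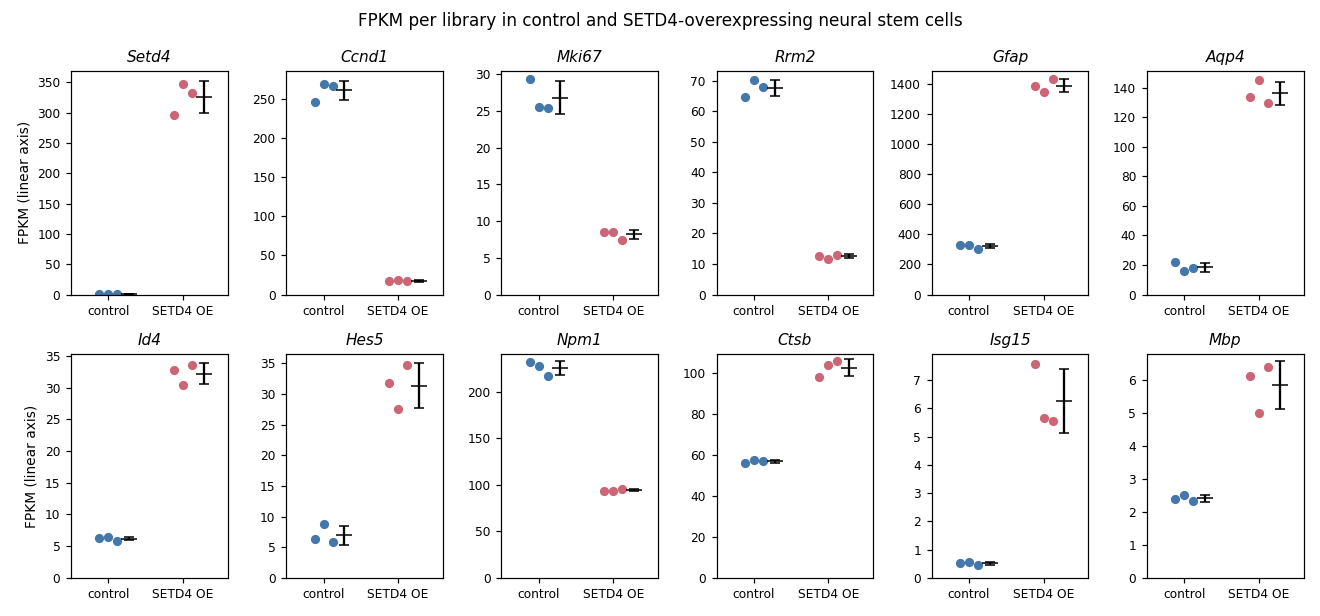
FPKM (y axes, linear and starting at 0) of 12 genes in each of the 3 control and 3 SETD4 OE libraries, with the mean and SD of each group in black beside the points. In each panel the 3 SETD4 OE points lie wholly above or wholly below the 3 control points, as for Gfap (321 and 1388 FPKM) and Mki67 (26.8 and 8.18 FPKM).

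The lower cell cycle genes were not accompanied by higher CDK inhibitors as a group. Of 8 members 5 fell and 1 rose (adjusted p = 0.240), with Cdkn2a going from 35.5 ± 4.08 to 10.3 ± 1.44 FPKM, Cdkn2b from 25.6 ± 4.28 to 10.4 ± 1.94 FPKM and Cdkn2d from 17.5 ± 3.63 to 9.34 ± 1.01 FPKM. The member that rose, Cdkn1b (p27), had a log2 fold change of 0.46, and Cdkn1a (p21) did not pass at -0.13; both were picked after their values were seen. Of 22 targets of p53, 5 rose and 10 fell (7 and 6 with upper-quartile scaling; adjusted p = 0.460), with Ddias at -1.18, Sesn1 at 1.09 and Plk2 at -1.04 on the log2 scale. Among the heterochromatin and lysine methyltransferase genes 5 of 26 rose and 12 fell (6 and 13 when adjusted over the list alone, 9 and 9 with upper-quartile scaling, 8 and 10 with quantile normalization; adjusted p of the list 0.331). Kmt5a, which monomethylates histone H4 at lysine 20, fell from 26.5 ± 0.942 to 10.5 ± 0.284 FPKM (log2 fold change -1.26, SE 0.05). Kmt5b, which with Kmt5c adds further methyl groups to the same residue, rose from 5.10 ± 0.213 to 6.78 ± 0.0774 FPKM (log2 fold change 0.35, SE 0.05, adjusted p = 1.293e-03, limma). Kmt5c was at 12.5 ± 0.706 and 14.4 ± 0.919 FPKM (log2 fold change 0.20, SE 0.07, adjusted p = 0.0386, limma), a call that was lost without control replicate 1 (adjusted p = 0.0801), control replicate 3 (0.130), SETD4 OE replicate 1 (0.127) or SETD4 OE replicate 3 (0.0788), and that ranged from 0.00369 to 0.130 over all alternatives. The maintenance DNA methyltransferase gene Dnmt1 fell from 24.7 ± 1.05 to 9.79 ± 0.255 FPKM, and Trim28, a heterochromatin co-repressor, from 97.2 ± 2.91 to 52.98 ± 1.85 FPKM.

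Signalling lists moved in both directions. In the Notch list 6 of 16 rose and 6 fell (8 and 4 with upper-quartile scaling; median 0.09, mean -0.02, adjusted p = 0.645). The ligand gene Jag1 fell from 19.9 ± 0.373 to 5.34 ± 0.436 FPKM, the receptor gene Notch2 rose from 7.22 ± 0.160 to 15.2 ± 0.816 FPKM, and Mfng rose from 0.640 ± 0.0023 to 1.77 ± 0.177 FPKM. In the BMP and TGF-beta list 8 of 20 rose and 6 fell (3 lower under the replicate block, with upper-quartile scaling or without control replicate 1; adjusted p = 0.326), with the receptor gene Bmpr1b at 1.65 and the ligand gene Bmp6 at 1.22 on the log2 scale. In the immediate early list 8 of 20 rose and 7 fell (median 0.04, mean -0.04, adjusted p = 0.619), with Fos rising from 12.2 ± 0.864 to 40.9 ± 1.66 FPKM, Ier3 falling from 26.5 ± 1.95 to 7.81 ± 0.361 FPKM and Arc from 13.3 ± 1.22 to 3.66 ± 0.768 FPKM.

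In all, 11 of the 24 tested lists passed with the preset correlation, 6 higher and 5 lower, and 2 passed with an estimated correlation, quiescent neural stem cell and mitosis. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Rescaling to a common upper quartile turned the split of changed genes to 4429 higher and 3255 lower and moved the median log2 fold change of all tested genes from -0.06 to 0.07, so that directions near 0 depend on the scaling, while the medians of the 11 lists kept their sign under each of the 4 other scalings.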

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

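Of the alternatives here, the 4 scalings, limma-voom on recovered reads and limma's treat were tests chosen only after the data were seen; tests of added lists and of explanations chosen after the results are named with them. Other normalizations and tests set in advance for deposited read counts were not run, since the tables hold FPKM. The count of 7790 changed genes ranged from 5256 (genes with a mean of at least 5 FPKM) to 8032 (no low-value filter) over 16 settings that kept the threshold, and from 6637 to 7874 when each library was left out. It was 1177 with a log2 fold change above 1 also required, and 1907 with limma's treat against 0.5. The share of changed genes that were higher was 43.4% and went to 57.6% with upper-quartile scaling. The count of 11 gene lists moved to 17 without the low-value filter, to 2 with an estimated correlation and to 22 with fry, which asks another question, and was 11 whichever library was left out. Setd4 kept its rise in each setting, with a log2 fold change of 7.19 to 8.17. Replicate numbers are shared between groups, but same-number deviations had correlations of -0.066, -0.229 and 0.077, and not every sample correlated best with its own number, so the numbers were not taken to pair the samples. With the replicate block 6941 genes changed, 6832 of them shared with the unblocked fit, 11 lists passed, and Setd4 was at 7.25. Of 1279 values of the other named genes under alternatives none changed sign and 7 lost the call, all of them Kmt5c, which lost it without the filter, under the block, with median-of-ratios scaling and on leaving out 4 of the libraries in turn; the cause was not tested. Of 379 list medians 8 gained a call, 3 of them the astrocyte list, and 5 changed sign, none of them past the threshold. These were the activated stem cell list at -0.34 and the immediate early list at -0.18 among genes with a mean of at least 5 FPKM, where fewer members are tested, and the immediate early list again on leaving out a library (-0.031 to 0.082, with -0.00075 and -0.013 between). Lists with fewer than 5 tested members in a compared setting were not counted. Among these, the pericyte, smooth muscle and fibroblast list went from 0.64 to -0.22 and the NF-kappaB list from 0.14 to -0.09 under that filter. Without a filter, the microglia list went from -0.72 to 0.07 and the endothelial list from -1.45 to 0.02. Depth limits the shortest genes, with 53 called genes under 200 bases resting on fewer than 20 reads.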

Other observations

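Several lists were chosen after the main results were seen, and their adjusted p-values come from limma's camera over these added lists. Genes of cytosolic ribosomal proteins fell in 71 of 76 cases and rose in none (75 lower when adjusted over the list alone), with a median log2 fold change of -0.74 and a summed level of 23010 ± 2456 FPKM in the controls and 13654 ± 1188 FPKM in SETD4 OE. Their adjusted p was 4.388e-12 with the preset correlation and 0.386 with an estimated correlation, the median stayed between -0.76 and -0.48 under 4 other scalings, and single members are uncertain because many have processed pseudogenes. Tubulin, actin and related cytoskeletal genes fell in 9 of 12 cases and rose in none (1 higher with upper-quartile scaling; median -0.57, and -0.33 with quantile normalization; adjusted p = 0.405 with an estimated correlation), led by Tuba1b (314 to 105 FPKM) and Tubb6 (92.6 to 31.1 FPKM).

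Target genes of FOXO transcription factors rose in 12 of 16 cases and fell in 3 (median 0.55; adjusted p = 0.250 with an estimated correlation). The apoptosis gene Bcl2l11 rose from 2.01 to 12.1 FPKM, the phosphoinositide 3-kinase inhibitor gene Pik3ip1 from 5.49 to 21.2 FPKM, Sesn3 from 15.1 to 43.2 FPKM and Txnip from 19.9 to 55.1 FPKM, while Irs2 fell from 30.5 to 16.0 FPKM. Genes of MHC class I antigen presentation rose in 8 of 12 cases and fell in none (median 0.51; adjusted p = 0.302 with an estimated correlation), among them B2m (88.7 to 126 FPKM), H2-D1 (19.3 to 34.2 FPKM) and Tapbp (6.47 to 13.9 FPKM). Medians of the FOXO and MHC lists stayed above 0 under the 4 other scalings, at 0.53 to 0.69 and 0.49 to 0.64. Genes of nuclear-encoded oxidative phosphorylation showed 1 of 83 higher and 20 lower (10 lower when adjusted over the list alone, and 10 to 32 lower when 1 library was left out), but 4 higher and 10 lower with upper-quartile scaling and 11 higher and 6 lower with quantile normalization, so no direction is claimed (median -0.17, and 0.02 with quantile normalization; adjusted p = 0.691 with an estimated correlation).

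For the patterns below, the tests of the authors' scaling, of p53 and of both explanations of the interferon genes were chosen after the results were seen. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7790 genes and the highest of the others 0, so that 1 of the 10 splits reached the real count; at an unadjusted p under 0.05, limma gave 8368 genes in the real split and 62 to 425 in the others. For the gene lists the real split gave 11 and the others 7 to 11, and 3 of the 10 splits reached 11. Each of the other splits placed control and SETD4 OE libraries together on each side. The difference between the groups therefore widened the spread within each side, and part of it remained between the sides. Neither the gene counts nor the list counts of these splits show what chance would give, and no conclusion is drawn from them.

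The first pattern is the fall of all 55 tested cell cycle genes, with a median log2 fold change of -1.55. A bias of gene length and GC content is argued against, since removing that trend left the median at -1.49 (quartiles -1.81 and -1.26). The choice among scalings moved the fall little. Under 4 other scalings the highest median of the members was -1.42, and the median of all tested genes ran from -0.07 to 0.07. Each of these scalings takes totals, typical genes or distributions as equal between libraries, so a change in total RNA per cell could not be seen and was not tested. Activation of p53 was not seen in its target Mdm2, which fell (log2 fold change -0.25, SE 0.05) and stayed below 0 under each alternative. Mdm2 no longer passed limma with upper-quartile scaling (adjusted p = 0.148) or quantile normalization (adjusted p = 0.305). Cdkn1a did not pass at -0.13 (SE 0.09). Of 22 p53 targets 5 rose, among them Sesn1 (1.09), and 10 fell (7 and 6 with upper-quartile scaling). The targets thus went both ways, and no conclusion on p53 is drawn. A candidate explanation is lower output of the ERK MAPK pathway. It was proposed from 4 of its targets (median -2.59), among them the G1 cyclin gene Ccnd1. Of 6 others not looked at before 5 fell (median -1.13), among them Etv4 (38.1 to 15.1 FPKM), Etv5 (99.8 to 44.7 FPKM) and Spry2 (92.2 to 56.4 FPKM). Of all 12994 tested genes 4406 fell. Epha4 rose (1.13), Fos rose (1.67) and Egr1 did not pass (0.11), and the adjusted p of the 6 (limma camera) was 0.386 with an estimated correlation. The 6 were measured in the same libraries as the 4, so they are not an independent check. Lower ERK MAPK output remains a hypothesis, since fewer cycling cells, an action of SETD4 on cell cycle genes and a lower response to growth factors were not separated. Because the groups differ in the virus given, an unequal dose of virus or viral RNA cannot be told apart from an effect of SETD4. That limit holds for the cell cycle genes and for every other difference between the groups.

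The second pattern is the rise of all 21 tested interferon response genes. RNA of immune cells in the SETD4 OE cultures cannot be ruled out: of the microglia and macrophage genes Cd68 fell from 6.94 to 3.75 FPKM, but the other 17 together rose 2.05 times (SE 0.227), from 2.19 to 4.50 FPKM, while the interferon genes summed to 45.4 and 134.7 FPKM. An unequal dose of virus or viral RNA cannot be told apart from an effect of SETD4, because 0 listed features were of the virus or of GFP and each virus was given to 1 group alone.

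The third pattern lies within the controls. Control replicate 1 had 3.78% of its reads on mitochondrially encoded genes, against 2.45% in both other controls and 3.52% to 3.73% in SETD4 OE, and leaving it out raised the number of called genes among 13 mitochondrially encoded ones from 2, mt-Nd4 and mt-Nd6 (0 when adjusted over the list alone), to 8, whereas leaving out any other library gave 0 (SETD4 OE replicate 2) to 2 (control replicate 3). RNA of SETD4 OE cells in that library is argued against, since over the 1284 nuclear genes that were called without it and changed by more than 1 on the log2 scale the library lay at 0.062 of the way from the other controls to SETD4 OE (quartiles -0.022 and 0.157) and at -0.027 for Setd4, but at a median of 1.08 for the 13 mitochondrially encoded genes, which ranged widely (-0.066 to 3.07). RNA quality and the state of that culture were not tested, and the design gives no biological explanation for a difference within the controls.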
